A study of Mus musculus with 48 samples.

How the data were processed

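RNA of the striatum, the deep forebrain region made mostly of projection neurons, was sequenced for 48 mice aged 4 months, per the labels. The mice came from a cross of Q140 mice, in which a Htt allele carries an engineered expanded CAG repeat, with mice lacking Mlh1, a DNA mismatch repair gene. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy kit and the libraries were made with the Illumina TruSeq stranded protocol, all mice being on a C57BL/6 background. Genotype, sex and replicate numbers were taken from the labels alone, which gave 6 genotype groups with each library from a separate mouse. The labels also gave each library's well on a plate of 48 wells and a code whose first number was shared by some animals, with a meaning that the labels do not state.

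The deposited count table holds the authors' whole-number read counts per Ensembl gene and library, without normalization. The deposited FPKM table holds the same values rescaled by the authors: for 35596 of the 35597 genes with a count in 2 or more libraries, the ratio of the FPKM value to the gene's share of counts was constant over libraries to within a relative difference of 1e-06. The submitters' processing notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 and the genome builds GRCm38 and mm10. The step that each tool served, the strand setting of the counting and the annotation release are not given in the sources used here. Gene symbols and positions were taken from the GENCODE M21 annotation of GRCm38, in which 48349 of the 48795 gene identifiers were found, all on the same chromosome and 48335 on the same strand as in the count table. Each library held 44 to 55.4 M counts (1 M is 1e+06). Genes with near-identical copies, such as clustered protocadherins and MHC class I genes, and genes that overlap others carry an added uncertainty, because the counting may have split or dropped their shared reads.

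Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr at its default settings, which kept 21331 genes, and libraries were scaled by TMM factors. A quasi-likelihood model with the 6 genotype groups and sex was fitted to all 48 libraries, so that all contrasts shared an estimate of the spread. The contrasts were the Q140 effect on each of the 3 Mlh1 genotypes, the effect of each Mlh1 genotype with and without Q140, the difference of the Q140 effect between Mlh1 genotypes (the interaction), the Q140 effect averaged over the 3 Mlh1 genotypes and, in a model of genotype by sex, the difference of the Q140 effect between females and males. P-values were adjusted by the Benjamini-Hochberg method over all tested genes of a contrast, and a gene was called at an adjusted p under 0.05. By chance alone, a share of about 0.05 of the tested genes would have an unadjusted p under 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are counts per 1 M counts of the TMM-scaled library, and log2 CPM values were made with a prior count of 2.

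Genes were named by a fixed rule: for each contrast, among called genes with a mean of at least 1 CPM and a symbol that is not a predicted name, the 12 largest rises and the 12 largest falls; up to 4 members with the smallest p of each list described; Mlh1 and Htt; the 5 smallest p of an interaction with no call; and Xist and Ddx3y for the sex check. The text prints part of the genes so picked, those with a known function first, and gives the others as counts. For each of 25 gene lists, members were counted, adjusted over all genes and over the list alone. The lists held mismatch repair genes, striatal projection neuron identity genes, markers of direct-pathway (D1) and of indirect-pathway (D2) neurons, immediate early genes, homeobox and other developmental transcription factors, clustered beta protocadherins, cell cycle, p53 and DNA damage, type I interferon, MHC class I and antigen presentation, sterol biosynthesis, heat shock and mitochondrial respiratory chain genes, markers of astrocytes, oligodendrocytes, oligodendrocyte precursors, microglia, endothelial and mural cells, cortical excitatory neurons, striatal interneurons, choroid plexus and ependyma, and pallidal, septal, thalamic and hypothalamic neurons, and the neighbours of Mlh1 and of Htt, which were set by name and not by a distance. Some genes stand in more than 1 list, such as Drd1 and Penk. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 225 tests of 25 lists in 9 contrasts, and with camera at an estimated correlation and with fry, which tests whether a list's genes move, on balance, in a direction. Camera called 77 of the 225 tests, 0 of them with an estimated correlation, and fry called 7.

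A signature score was computed per library as the mean log2 CPM of the 1079 genes that rose less the mean of the 1021 genes that fell in the averaged Q140 effect. Differences in the score were tested by exact two-sided permutation of genotype labels, and differences of the Q140 effect by exact permutation of the Mlh1 labels within knock-in and within other libraries. Intervals of 95% came from 10000 bootstrap resamples of libraries within groups. The groups, the model, the lists, the naming rule and the alternatives were set before the data were examined. The alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, no sex term, a block for sex and replicate number, the animal code as a random block, plate row and column, surrogate variables from sva 3.50.0, an adjusted p under 0.1, limma on log2(FPKM + 0.1), and each library left out in turn. Added after the data were seen were marker scores of cortex and choroid plexus as covariates, a fit without 5 libraries at odds with their group, exact permutation tests of list scores, list tests without libraries that stood apart, a mixed model of the signature score with the animal code as a random intercept, and a score of 14 called genes near Htt. In each group, the gap from the most extreme library to the next was set against Dixon's 95% critical value.

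The test was run on simulated counts made from the real means and library sizes, with 200 genes changed. For Q140 vs WT, 42%, 58%, 72% and 88% of the 50 genes changed 1.2-, 1.3-, 1.5- and 2-fold were recovered among 21331 genes, with 5 false calls of 135. For Q140 Mlh1-/- vs Mlh1-/-, the shares were 50%, 62%, 78% and 84%, with 4 false calls of 141. Each gene was drawn independently, with the same dispersion in all groups. Correlated genes, RNA of other brain regions, plate or animal code effects and a larger spread in Q140 groups were not simulated. The false calls may therefore be more frequent in the real data.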

Results

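The series compared the striatum of Q140 mice, a knock-in model of Huntington's disease, with and without Mlh1, a gene of DNA mismatch repair. Q140 mice carry a Htt allele with an expanded CAG repeat beside a normal allele. Striatal RNA was sequenced at 4 months of age in 8 wild-type (WT), 7 Q140, 9 Mlh1+/-, 8 Q140 Mlh1+/-, 7 Mlh1-/- and 9 Q140 Mlh1-/- mice, with 3 to 5 animals of each sex per group. The libraries held 44 to 54 M counts in WT, 47.2 to 53.8 M in Q140 and 44.9 to 55.4 M in Mlh1+/- mice. They held 45.3 to 51.9 M in Q140 Mlh1+/-, 44.5 to 52.5 M in Mlh1-/- and 44.5 to 51.5 M in Q140 Mlh1-/- mice. Xist, which silences the second X chromosome, lay between 842 and 1570 CPM in the 24 females and between 0.201 and 25.6 CPM in the 24 males. Y-linked Ddx3y lay between 0 and 1.06 CPM in females and between 48.9 and 66.6 CPM in males. The most similar pair of libraries within a group, Mlh1+/- M2 and M4, differed by a chi-square of 5.53 per degree of freedom, so each library counted as a separate animal. Some libraries held high levels of genes of other brain regions. WT M3 held 2530 CPM of Ttr, the transthyretin gene of the choroid plexus, against a median of 11.1 CPM in the other WT libraries, and Q140 Mlh1-/- F5 held 141 CPM. Slc17a7, the vesicular glutamate transporter of cortical neurons, was highest in Mlh1+/- F1 with 140 CPM, Mlh1+/- M1 with 124 CPM, Mlh1-/- F1 with 74.7 CPM and Mlh1+/- F3 with 64.3 CPM. Prkcd, a kinase gene of thalamic neurons, was highest in Q140 Mlh1+/- M1 with 62.2 CPM.

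The mean level of Mlh1 was lower with each lost allele, in mice with and without the Q140 allele. The loss of both alleles was called by edgeR in both settings. The loss of a single allele was called without the Q140 allele, though not without any of 12 libraries in turn, and not on the Q140 allele (adjusted p = 0.106). Mlh1 (ENSMUSG00000032498, chromosome 9, 111228228 to 111271791, GRCm38) measured 13.8 ± 2.4 CPM in WT (SD, n = 8), 8.37 ± 1.72 CPM in Mlh1+/- (n = 9) and 3.03 ± 0.183 CPM in Mlh1-/- mice (n = 7). On the Q140 allele the levels were 13.3 ± 2.91 CPM (n = 7), 8.03 ± 1.99 CPM (n = 8) and 3.25 ± 0.408 CPM (n = 9). The heterozygous means were 60.6% of the matching Mlh1 wild-type mean in both comparisons, and the null means were 22% and 24.5%. Counts per gene do not show which exons the remaining reads came from. The 16 Mlh1-/- libraries reached at most 3.97 CPM, and the lowest Mlh1+/- library, F2, held 4.23 CPM against a median of 8.93 CPM in the rest of its group. Htt (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) differed by less than the test could call with the Q140 allele, with log2 fold changes of -0.06 ± 0.04 on wild-type Mlh1 (SE, adjusted p = 0.413), -0.09 ± 0.04 on Mlh1+/- (adjusted p = 0.145) and 0.05 ± 0.04 on Mlh1-/- (adjusted p = 1).

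**Figure D1:**
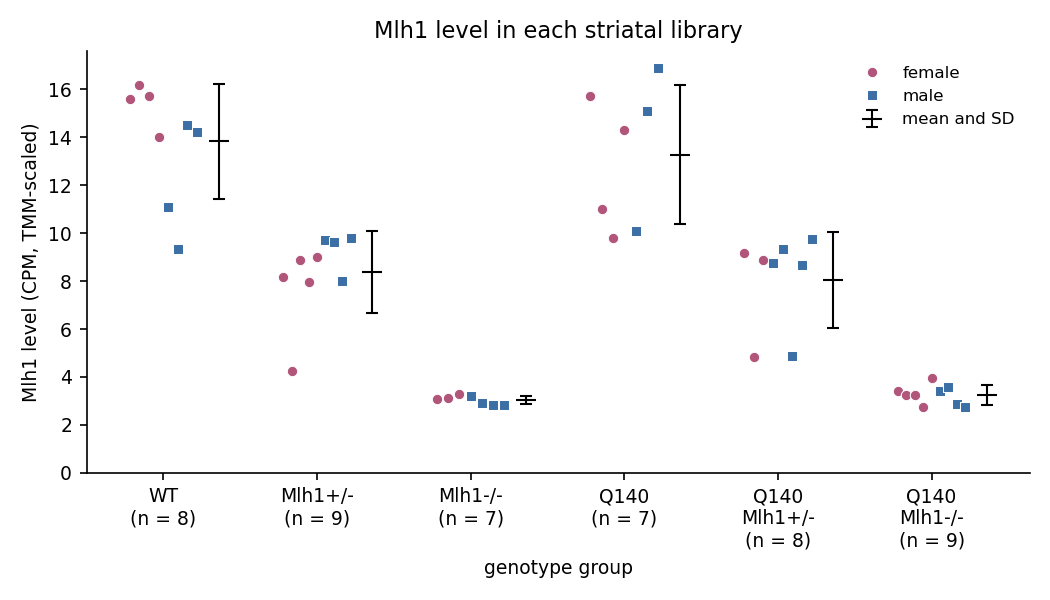
Mlh1 level in CPM on the vertical axis for each of the 48 libraries, by genotype group on the horizontal axis, with females as circles, males as squares and the mean with its SD at the right of each group. All 16 Mlh1-/- libraries lie at or below 3.97 CPM and the lowest Mlh1 wild-type library lies at 9.34 CPM.

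The first comparison, Q140 against WT mice, asked what the expanded allele changed on wild-type Mlh1. Of the genes that mark striatal projection neurons, 18 of 48 fell, and of clustered protocadherins 3 of 21 rose. Penk, the enkephalin precursor of indirect-pathway neurons, fell from 1880 ± 108 CPM in WT to 1220 ± 161 CPM in Q140 mice (SD, n = 8 and 7; log2 fold change -0.63 ± 0.08, adjusted p = 1.86e-05). Ppp1r1b, which encodes the dopamine-signalling protein DARPP-32, fell from 2320 ± 96.1 CPM to 1870 ± 166 CPM (log2 fold change -0.31 ± 0.06, adjusted p = 0.0013). The largest rise of the genes named was in Slitrk6, a synaptic membrane protein gene, from 4.36 ± 0.693 CPM to 7.9 ± 1.51 CPM, which is 1.81-fold (adjusted p = 0.000219). In all, 615 of 21331 genes were called, 303 higher and 312 lower, with a median absolute log2 fold change of 0.25 and 85 genes beyond 1.5-fold. Among the largest rises were also Tnnt2, a troponin gene, by 0.78 ± 0.18 on the log2 scale, Pcdh20, a protocadherin gene, by 0.66 ± 0.13, and Vill by 0.62 ± 0.12. So were Cnih3, an AMPA receptor auxiliary subunit gene, by 0.61 ± 0.15, and Htr2a, a serotonin receptor gene, by 0.58 ± 0.10. Among the largest falls were Krt9, a keratin gene, with -0.91 ± 0.13, and Plk5, a polo-like kinase gene, with -0.85 ± 0.14. Ddit4l, an inhibitor of mTOR signalling, fell with -0.80 ± 0.16, and Trib3, a stress-induced pseudokinase gene, with -0.80 ± 0.20. The genes with the greatest fall were of the choroid plexus. Ttr had a log2 fold change of -4.49 ± 1.02 and Slc4a5, a bicarbonate transporter gene, of -3.75 ± 0.88, and without WT M3 the values were -0.32 and -0.58, with no call. Without Q140 M2, Cnih3 stood at 0.58 and Trib3 at -0.72 with no call, and Trib3 had none either without Q140 F1 (-0.73) or WT M1 (-0.68).

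Of the 48 striatal projection neuron identity genes measured, 18 fell, none rose and 30 were not called, and adjusted over the list alone 37 fell and 1 rose. The list fell as a group (median log2 fold change -0.22, camera adjusted p = 2.42e-21; adjusted p = 0.428 with an estimated correlation). Beside Penk and Ppp1r1b, Adcy5, the main striatal adenylyl cyclase gene, stood at -0.33 ± 0.06 (adjusted p = 0.00143) and Pde1b, a phosphodiesterase gene, at -0.33 ± 0.06 (adjusted p = 0.00178). Of 15 markers of indirect-pathway neurons, 4 fell and none rose, and adjusted over the list alone 7 fell (median -0.17, camera adjusted p = 0.000105; adjusted p = 0.337 with an estimated correlation). The 4 were Penk, Gpr6, an orphan receptor gene, with -0.30 ± 0.06, the adenosine receptor gene Adora2a with -0.42 ± 0.08, and the dopamine receptor gene Drd2 with -0.28 ± 0.07. Direct-pathway markers moved both ways: of 15, 3 rose and 2 fell, among them Stmn2, a microtubule regulator gene, with 0.36 ± 0.08, the transcription factor gene Isl1 with 0.23 ± 0.05 and the dopamine receptor gene Drd1 with -0.28 ± 0.07. Adjusted over the list alone, 4 rose and 3 fell. The list's median was -0.01, its mean 0.02 and camera's direction up, without a call (adjusted p = 0.762). Of 21 clustered beta protocadherins, neuronal adhesion genes of a single gene cluster, 3 rose and none fell, and adjusted over the list alone 11 rose. Their median was 0.19 (camera adjusted p = 2.06e-08; adjusted p = 0.337 with an estimated correlation) and Pcdhb9, which lost its call without WT F2 (0.24), stood at 0.27 ± 0.07. Fry called these lists except the direct-pathway markers, at adjusted p = 0.0349 for the identity genes, 0.0175 for the indirect-pathway markers and 0.0237 for the protocadherins.

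Lists of other cell types and pathways were tested too. Endothelial and mural markers had a median of -0.10 (camera adjusted p = 0.00128; adjusted p = 0.593 with an estimated correlation), and 2 of 19 fell, or 5 adjusted over the list alone. Choroid plexus and ependymal markers had a median of -1.74 (camera adjusted p = 0.0179; adjusted p = 0.791 with an estimated correlation). Of these 17 markers 8 fell, or 11 adjusted over the list alone, and without WT M3 no member was called and the median was -0.18 (adjusted p = 0.938). Camera also called type I interferon genes (30 members, median -0.17, adjusted p = 7.53e-05; adjusted p = 0.584 with an estimated correlation) and oligodendrocyte markers (22 members, median -0.14, adjusted p = 0.00308; adjusted p = 0.791 with an estimated correlation). It called microglia markers (20 members, median -0.04, adjusted p = 0.0444; adjusted p = 0.791 with an estimated correlation) as well. Mitochondrial respiratory chain genes were called with a positive median of 0.05 (32 members, adjusted p = 5.04e-05; adjusted p = 0.744 with an estimated correlation). No gene of these 4 lists was called, and adjusted over the list alone 1 microglia marker fell. The other 16 lists, counting the direct-pathway markers, were not called. In 10 of them no member was called, and camera's adjusted p was 0.0531 for the 27 cell cycle genes (median -0.12), 0.319 for 17 MHC class I genes (-0.06), 0.702 for 21 astrocyte markers (-0.01), 0.342 for 18 cortical markers (0.11) and 0.28 for 13 homeobox genes (-0.12). It was 0.762 for 18 mismatch repair genes (0.02), 0.536 for 10 oligodendrocyte precursor markers (-0.08), 0.195 for 15 pallidal and thalamic markers (0.07), 0.0844 for 25 sterol genes (-0.06) and 0.598 for 19 interneuron markers (0.03). In the remaining 5 lists some members were called. The immediate early genes (24 members, median -0.06, adjusted p = 0.592) held Homer1, a postsynaptic scaffold gene, at -0.40 ± 0.10. Adjusted over the list alone 2 fell. The heat shock genes (20 members, median -0.01, adjusted p = 0.883) held 1 gene that fell, and the p53 and DNA damage genes (26 members, median 0.01, mean -0.02, camera up, adjusted p = 0.813) held Rrm2b, a ribonucleotide reductase gene, at 0.17 ± 0.04. Adjusted over the list alone, 1 heat shock gene rose and 1 fell, and 1 p53 gene rose. Of 25 neighbours of Htt, 3 fell (3 adjusted over the list alone; median 0.02, mean -0.02, camera down, adjusted p = 0.912). Of 42 neighbours of Mlh1, Vill rose and Arpp21, at -0.31 ± 0.07, fell (2 and 2 adjusted over the list alone; median -0.03, adjusted p = 0.497).

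The size of this comparison rested in part on 2 libraries. Without Q140 F1, 235 genes were called, 232 of them among the 615. Without Q140 M2, 268 genes were called, 264 of them among the 615. The identity genes then held 8 and 9 calls, the protocadherins, the endothelial markers and the neighbours of Htt none, and microglia markers were not called as a list without Q140 F1 (adjusted p = 0.0646). Of the genes named here, Drd1 stood at -0.24 without either, Drd2 at -0.26 and -0.22, Homer1 at -0.36 and -0.34, Arpp21 at -0.26 and -0.26, and Pcdhb9 at 0.23 and 0.24, without a call. With plate row and column as factors 329 genes were called, and with 10 surrogate variables 9. Limma on log2(FPKM + 0.1) called 815 genes, 567 higher and 248 lower, so the near balance of rises and falls was not kept there, and the cause was not tested.

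On a single Mlh1 allele, the Q140 allele lowered 24 of the 48 projection neuron genes and raised 11 of the 21 protocadherins. Penk fell from 1880 ± 177 CPM in Mlh1+/- mice to 1210 ± 199 CPM in Q140 Mlh1+/- mice (SD, n = 9 and 8; log2 fold change -0.63 ± 0.08, adjusted p = 3.19e-06). Ppp1r1b fell from 2340 ± 178 to 1820 ± 223 CPM (-0.36 ± 0.06, adjusted p = 5.33e-05), and Pcdhb13 rose from 9.06 ± 1.62 to 13.5 ± 1.56 CPM (0.58 ± 0.10, adjusted p = 0.000132). In all, 916 genes were called, 392 higher and 524 lower, with 83 beyond 1.5-fold. The rises included Slitrk6 with 0.84 ± 0.13 and Tnnt2 with 0.80 ± 0.17. They also included the transcription factor gene Zbtb16 with 1.07 ± 0.29, the desmosomal gene Dsg1c with 0.88 ± 0.19 and Nts, the neurotensin precursor gene, with 0.65 ± 0.17. The falls included Krt9 with -0.82 ± 0.12, Plk5 with -0.84 ± 0.13, and Ddit4l with -0.78 ± 0.15. Further falls were in the transcription factor gene Mafa with -1.13 ± 0.22, the small GTPase gene Rasl10a with -0.85 ± 0.11 and the ligand gene Wnt4 with -0.84 ± 0.18. Xist had the largest fold among called genes of the naming rule, 1.65 ± 0.49 (adjusted p = 0.0384), and 0.32 without a call when Q140 Mlh1+/- M3 was left out. Its call also ended without any of Mlh1+/- F3, F4, F5, M1, M2, M3 or M4 (1.58 to 1.69), that of Zbtb16 without Q140 Mlh1+/- M1 (0.96) or M5 (0.97), and those of Nts (0.55) and Srebf2 (-0.16) without M1. The count was 609 without Q140 Mlh1+/- F1 and 577 without M1, and it was 234 with plate row and column as factors and 13 with 10 surrogate variables. Limma on log2(FPKM + 0.1) called 1189, of which more were higher (729) than lower (460).

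In the same comparison 24 of the 48 identity genes fell and none rose, and adjusted over the list alone 36 fell and 1 rose (median -0.24, camera adjusted p = 2.63e-28; adjusted p = 0.337 with an estimated correlation). Among them were Pde1b with -0.38 ± 0.06, the potassium channel gene Kcnj4 with -0.32 ± 0.05, the muscarinic receptor gene Chrm4 with -0.36 ± 0.06 and Drd1 with -0.31 ± 0.06. Of 15 indirect-pathway markers 5 fell, including Gpr6 with -0.34 ± 0.06, Adora2a with -0.45 ± 0.08 and Upb1, an enzyme gene of pyrimidine breakdown, with -0.48 ± 0.11, and adjusted over the list alone 2 rose and 6 fell (median -0.08, camera adjusted p = 0.00289; adjusted p = 0.471 with an estimated correlation). Direct-pathway markers again moved both ways, with 2 of 15 higher (Stmn2 at 0.32 ± 0.07 and Isl1 at 0.22 ± 0.05) and 3 lower (median 0.01, mean -0.02, camera down, adjusted p = 0.703). Of 21 beta protocadherins 11 rose, or 17 adjusted over the list alone, and all 21 had a positive fold (median 0.24, camera adjusted p = 2.37e-16; adjusted p = 0.144 with an estimated correlation). Pcdhb3 stood at 0.45 ± 0.08, Pcdhb9 at 0.37 ± 0.06 and Pcdhb21 at 0.39 ± 0.07. Camera further called endothelial and mural markers (median -0.12, adjusted p = 0.00175; adjusted p = 0.631 with an estimated correlation), where the smooth muscle gene Tagln fell with -0.40 ± 0.09. It called sterol biosynthesis genes (median -0.09, adjusted p = 0.00133; adjusted p = 0.706 with an estimated correlation), where the regulator gene Srebf2 fell with -0.17 ± 0.04. Also called were immediate early genes (median -0.20, adjusted p = 0.0226; adjusted p = 0.815 with an estimated correlation), where Homer1 fell with -0.47 ± 0.09, and microglia markers (median -0.05, adjusted p = 0.0179; adjusted p = 0.779 with an estimated correlation). Fry called the identity genes at adjusted p = 0.00866, the protocadherins at 0.000206 and the indirect-pathway markers at 0.0351. Rrm2b rose by 0.15 ± 0.04 and the respiratory chain gene Ndufs3 fell with -0.16 ± 0.04. Near Htt the adrenergic receptor gene Adra2c stood at -0.32 ± 0.05 and Whsc1, a histone methyltransferase gene, at -0.11 ± 0.03, 365.8 and 863.8 kb from Htt.

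With no Mlh1 allele, the test called few genes for the Q140 allele, and none of the identity genes or protocadherins. Penk measured 1770 ± 69.6 CPM in Mlh1-/- and 1490 ± 181 CPM in Q140 Mlh1-/- mice (SD, n = 7 and 9; log2 fold change -0.25 ± 0.08, adjusted p = 0.537), and Ppp1r1b 2120 ± 138 and 1990 ± 111 CPM. The test called 4 of 21331 genes, against 1132 at an unadjusted p under 0.05, a number near that from chance alone. Ttc3, a ubiquitin ligase gene, fell from 852 ± 24.4 to 776 ± 23.5 CPM (-0.14 ± 0.02, adjusted p = 0.015), and Pipox, a peroxisomal oxidase gene, from 6.09 ± 0.676 to 4.43 ± 0.692 CPM (-0.46 ± 0.09, adjusted p = 0.0473). Dpysl5, a gene of axon growth, rose from 52 ± 5.37 to 65.6 ± 6.97 CPM (0.33 ± 0.07, adjusted p = 0.0473). The pseudogene Gm2420, which was named after its values were seen, rose from 0.872 ± 0.139 to 1.57 ± 0.238 CPM (0.84 ± 0.16, adjusted p = 0.0473). Dpysl5 (chromosome 5, 30711564 to 30799375) and Gm2420 (chromosome 5, 32720330 to 32736194) lie within 10 Mb of Htt. DESeq2 called 5 genes, limma-voom 3, and the fit of these groups alone 0. With plate row and column as factors 0 genes were called. With 10 surrogate variables 8 were, against 9 in Q140 vs WT and 13 in Q140 Mlh1+/- vs Mlh1+/-, so the gap in counts between backgrounds rested on the model without them. Without Q140 Mlh1-/- M2 or without Mlh1-/- F2 no gene was called (Ttc3 at -0.13 in both). Without any of Q140 Mlh1-/- F2 or F4 or Mlh1-/- M1, M2 or M3 the count was 1, and without any of Q140 Mlh1-/- F1 or Mlh1-/- F1 or M4 it was 2. The folds stayed between 0.28 and 0.38 for Dpysl5, between -0.52 and -0.43 for Pipox and between 0.80 and 0.90 for Gm2420. The call of Dpysl5 ended in 13 of the 16 leave-outs, all but those of Q140 Mlh1-/- F5 and M1 and Mlh1-/- F3. That of Gm2420 ended in 9, without any of Q140 Mlh1-/- F1, F2, F4 or M2 or Mlh1-/- F1, F2, M1, M2 or M3. The call of Pipox ended in 11, without any of Q140 Mlh1-/- F2, F4, F5, M2 or M4 or Mlh1-/- F2, F3, M1, M2, M3 or M4.

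None of the 48 identity genes was called in Mlh1-/- mice, also adjusted over the list alone, with 29 negative and 19 positive folds (median -0.02, camera adjusted p = 0.483). Tac1, the substance P precursor gene, stood at 0.18 ± 0.07 (adjusted p = 0.742). No beta protocadherin was called, also adjusted over the list alone, but all 21 had a positive fold (median 0.16, camera adjusted p = 9.17e-12; adjusted p = 0.248 with an estimated correlation; fry adjusted p = 0.0793). Their mean Q140 effect was 0.152 here (exact permutation p = 0.0166, adjusted p = 0.148) and 0.182 on wild-type Mlh1. The difference of -0.03 was not called (exact permutation p = 0.677), which does not show that the effects were equal. The list mean was 2.925 log2 CPM in Mlh1-/- and 3.077 in Q140 Mlh1-/- mice, against 2.992 in WT and 3.175 in Q140 mice. Pcdhb15 stood at 0.23 ± 0.08 (adjusted p = 0.692) and Pcdhb3 at 0.23 ± 0.08 (adjusted p = 0.742). Camera also called oligodendrocyte markers (median -0.09, adjusted p = 0.000382; adjusted p = 0.789 with an estimated correlation), heat shock genes (median -0.05, adjusted p = 0.00551; adjusted p = 0.744 with an estimated correlation) and endothelial and mural markers (median 0.10, adjusted p = 0.00322; adjusted p = 0.694 with an estimated correlation). Without Q140 Mlh1-/- F5 the endothelial median was 0.03 (adjusted p = 0.235).

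Read across the 3 backgrounds, which share no library, the genes called in Q140 against WT mice moved alike on a single Mlh1 allele and less without Mlh1. Of the 615 genes, 600 (97.6%) had the same direction in Mlh1+/- mice and 363 were called there in that direction, against 13.2 from independent lists, and the median ratio of the effects was 0.85. In Mlh1-/- mice 491 (79.8%) had the same direction and 4 were called, against 0.0577, with a median ratio of 0.22. The ratios are lowered in both cases because the genes were chosen in Q140 against WT mice. Slitrk6 stood at 0.85 ± 0.13, 0.84 ± 0.13 and 0.22 ± 0.13 on wild-type Mlh1, Mlh1+/- and Mlh1-/-. In the same order, Krt9 stood at -0.91 ± 0.13, -0.82 ± 0.12 and -0.39 ± 0.12, and Plk5 at -0.85 ± 0.14, -0.84 ± 0.13 and -0.45 ± 0.13.

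**Figure D2:**
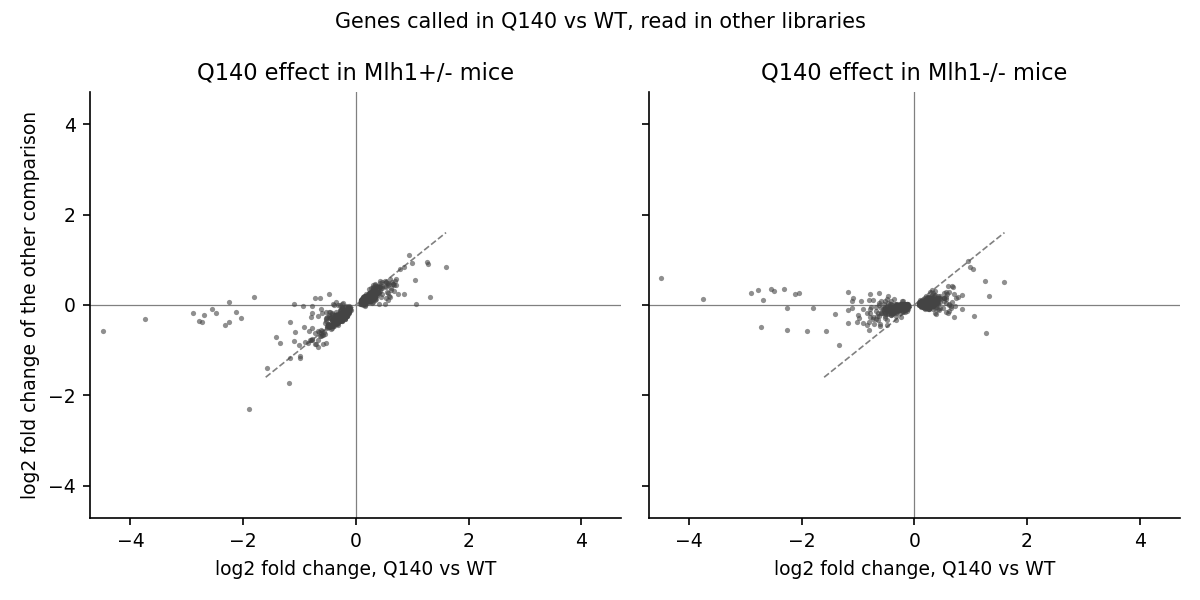
Log2 fold changes of the 615 genes called in Q140 against WT mice (horizontal axes) and of the same genes for the Q140 allele in Mlh1+/- (left) and Mlh1-/- mice (right, vertical axes), with the dashed line marking equal effects. Each point is a gene, and the median ratio of the effects is 0.85 at the left and 0.22 at the right.

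**Figure D3:**
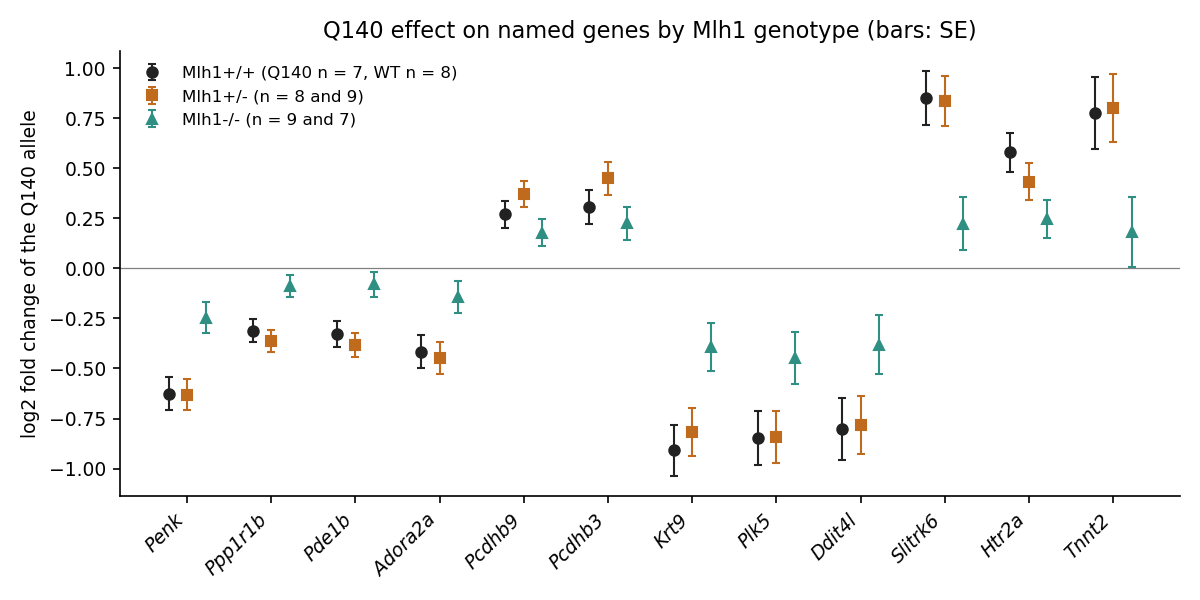
Log2 fold change of the Q140 allele with its SE for 12 named genes on the horizontal axis, in Mlh1 wild-type (black circles, n = 7 and 8), Mlh1+/- (orange squares, n = 8 and 9) and Mlh1-/- mice (green triangles, n = 9 and 7). Penk lies at -0.63, -0.63 and -0.25, and Slitrk6 at 0.85, 0.84 and 0.22.

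The interaction, which asks whether the Q140 effect differs with Mlh1 genotype, was read on the signature score and gene by gene. The Q140 allele raised the score by 0.42 in Mlh1 wild-type mice (0.02 ± 0.13 against -0.40 ± 0.02 log2 CPM, SD, n = 7 and 8, exact permutation p = 0.000155). The rise was 0.42 in Mlh1+/- mice (0.03 ± 0.14 against -0.40 ± 0.03, n = 8 and 9, exact p = 4.11e-05) and 0.18 in Mlh1-/- mice (-0.18 ± 0.10 against -0.36 ± 0.03, n = 9 and 7, exact p = 0.000437). The genes of the score were chosen on these libraries from the averaged effect, so these 3 p-values are not independent evidence of an effect. The effect in Mlh1-/- mice was smaller by -0.24 than in Mlh1 wild-type mice (exact permutation p = 0.000222), which left 43.2% of it (95% interval 27.3% to 63.3%). The interval held the genes fixed, so it leaves out their choice on these same libraries, which can raise the share. The share depended on the genes used: it was 22.5% (8.72% to 37.8%) on the genes called in Q140 vs WT alone, where selection lowers it, and 7.34% (-33.5% to 50.4%) on the identity genes. On the identity genes it also hung on single libraries, at 20.6% without Mlh1-/- F3 and -1.71% without Q140 Mlh1-/- F5. The other shares stayed between 38.9% and 47.6% on the full score and between 19.5% and 27% on the genes called in Q140 vs WT without each library in turn. In Mlh1+/- mice it differed by 0.005 (exact permutation p = 0.948), or 101% (73.8% to 138%). The score was lower in Q140 Mlh1-/- than in Q140 mice by -0.19 (exact p = 0.00297, n = 9 and 7) and higher in Mlh1-/- than in WT mice by 0.04 (exact p = 0.00948, n = 7 and 8). On the identity genes, with the sign turned, these differences were -0.072 (exact p = 0.232) and 0.118 (exact p = 0.00311; 0.091 without Mlh1-/- F3), so the small share there came more from the Mlh1-/- level than from the Q140 Mlh1-/- level. On the genes called in Q140 vs WT alone they were -0.315 (exact p = 0.00035) and 0.192 (exact p = 0.000622), and the choice of these genes on Q140 and WT libraries enlarges both.

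**Figure D4:**
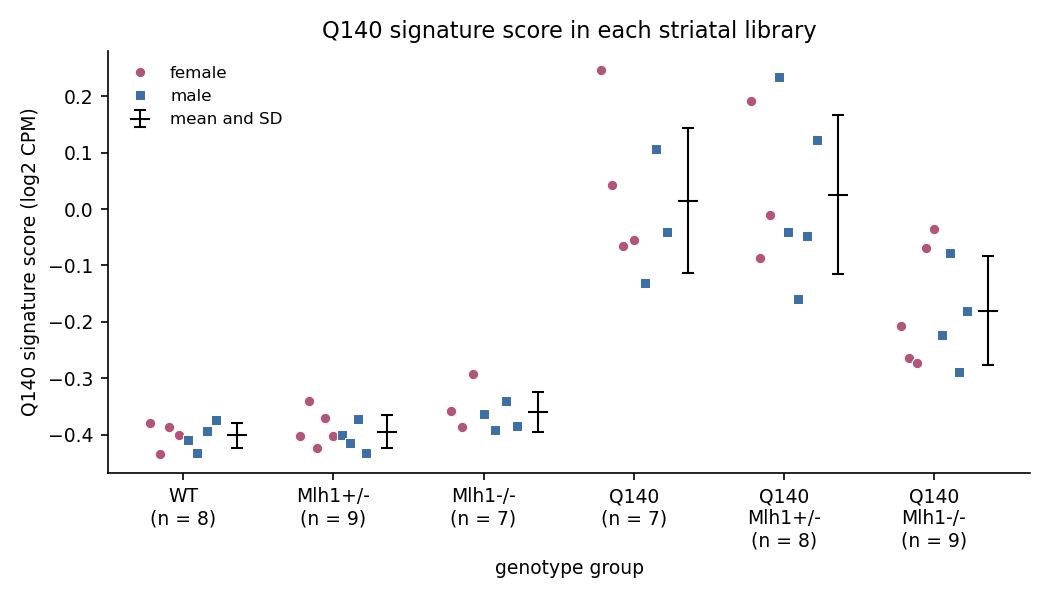
Q140 signature score in log2 CPM on the vertical axis for each of the 48 libraries by genotype group, females as circles and males as squares, with the mean and SD at the right of each group. WT libraries lie between -0.43 and -0.37, Q140 libraries between -0.13 and 0.25, Mlh1-/- libraries between -0.39 and -0.29 and Q140 Mlh1-/- libraries between -0.29 and -0.04.

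Single genes did not pass the interaction test with edgeR. In Mlh1-/- against Mlh1 wild-type mice 0 genes were called, with 1715 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0. The smallest p belonged to Tmem196 with -0.55 ± 0.11, Fut10, a fucosyltransferase gene, with -0.30 ± 0.06, and Prrg3 with -0.26 ± 0.06 (each adjusted p = 0.171), and to Slc17a5, the lysosomal sialic acid exporter gene, with -0.28 ± 0.06 and Tcerg1l with -0.73 ± 0.17 (each adjusted p = 0.416). Leaving out Q140 M1 gave 2 calls, and leaving out Mlh1-/- F2 or F3 gave 1. As a group, the identity genes had a more positive Q140 effect without Mlh1 (median difference 0.21, 44 of 48 positive, camera adjusted p = 5.25e-17; adjusted p = 0.471 with an estimated correlation), and adjusted over the list alone 14 were higher. Camera likewise called the endothelial markers (0.19, adjusted p = 4.82e-07; adjusted p = 0.337 with an estimated correlation) and the interferon genes (0.27, adjusted p = 1.07e-06; adjusted p = 0.471 with an estimated correlation). It also called the indirect-pathway markers (0.19, adjusted p = 0.000981; adjusted p = 0.428 with an estimated correlation). Adjusted over the list alone, 4, 0 and 1 members of these lists were higher. The protocadherins were not called (-0.06, adjusted p = 0.439). Without Q140 Mlh1-/- F5 the endothelial difference was 0.15 with 2 members, and without Mlh1-/- F3 no identity gene and no endothelial marker passed over the list alone. Camera called 6 lists in this interaction, not all named here. Exact permutation of list means did not call identity genes (0.19, adjusted p = 0.0986), endothelial markers (0.217, adjusted p = 0.128) or interferon genes (0.241, adjusted p = 0.126). Pallidal and thalamic markers (-0.401, adjusted p = 0.188) and interneuron markers (-0.172, adjusted p = 0.19) moved the other way, also without a call by that test. In Mlh1+/- against Mlh1 wild-type mice 0 genes were called, with 646 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. There camera called mitochondrial genes (-0.04, adjusted p = 7.35e-06; adjusted p = 0.705 with an estimated correlation) and protocadherins (0.10, adjusted p = 0.00762; adjusted p = 0.744 with an estimated correlation).

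Without the Q140 allele, the loss of a single Mlh1 allele gave a call for Mlh1 alone, and smaller effects on other genes are not excluded. Mlh1 fell by 0.72 ± 0.13 on the log2 scale (adjusted p = 0.0335, n = 9 and 8), the only call of 21331 genes, with 1423 at an unadjusted p under 0.05. The call ended without any of Mlh1+/- F1, F2, F3, F4, F5 or M3 or WT F1, F2, F3, F4, M3 or M4, the fold staying between -0.79 and -0.63 without each library of these groups, and DESeq2 called 1 gene and limma-voom 0. Cortical excitatory neuron markers had a median of 0.32 (18 members, none called, 8 higher adjusted over the list alone, camera adjusted p = 4.19e-06; adjusted p = 0.337 with an estimated correlation). The median was 0.08 (adjusted p = 0.142) without Mlh1+/- F1, M1 and F3, the libraries of this group with high Slc17a7. Choroid plexus markers had a median of -1.86 (none of 17 called, 14 lower adjusted over the list alone, adjusted p = 2.07e-06; adjusted p = 0.584 with an estimated correlation), and -0.10 (adjusted p = 0.18) without WT M3. Microglia markers were called with a median of 0.07 (adjusted p = 5.39e-05; adjusted p = 0.557 with an estimated correlation). On the Q140 allele, Mlh1 stood at -0.73 ± 0.14 in Q140 Mlh1+/- against Q140 mice (adjusted p = 0.106, n = 8 and 7), and edgeR called 0 genes, with 887 at an unadjusted p under 0.05, DESeq2 1 and limma-voom 0. Leaving out Q140 F3 or Q140 M1 gave 1 call, Mlh1. Camera called oligodendrocyte markers there (median 0.14, adjusted p = 3.31e-07; adjusted p = 0.706 with an estimated correlation), with all 22 folds positive.

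In mice without either Mlh1 allele, Mlh1 and the nearby gene Lrrfip2 were lower in both settings. Mlh1 had a log2 fold change of -2.19 ± 0.15 in Mlh1-/- against WT mice (adjusted p = 3.59e-14, n = 7 and 8) and of -2.03 ± 0.14 in Q140 Mlh1-/- against Q140 mice (adjusted p = 3.79e-14, n = 9 and 7). Lrrfip2, which lies 2.6 kb from Mlh1 on chromosome 9, fell from 27.1 ± 1.88 to 21.7 ± 0.891 CPM (-0.32 ± 0.05, adjusted p = 0.00155) and from 26.8 ± 2.12 to 21.6 ± 1.71 CPM (-0.32 ± 0.05, adjusted p = 0.000878). In Mlh1-/- against WT mice 13 genes were called, 10 higher and 3 lower. Tmie, a hair cell transduction gene 348.1 kb from Mlh1, rose by 0.58 ± 0.10, Tmem200a by 0.78 ± 0.17, Tcerg1l by 0.59 ± 0.13 and the transcription factor gene Ebf4 by 0.55 ± 0.12. Tmem145 rose by 0.62 ± 0.13 and Cd83, an immune surface protein gene, by 0.53 ± 0.10. Without Mlh1-/- F3, Tmem200a stood at 0.58, Tcerg1l at 0.46, Ebf4 at 0.39, Tmem145 at 0.44 and Cd83 at 0.38, all without a call, and these genes but not Mlh1, Lrrfip2 and Tmie lost their call without further libraries too. Dclk3, a kinase gene 167.3 kb from Mlh1, stood at -0.40 ± 0.10 (adjusted p = 0.0962). Epm2aip1 lies nearer to Mlh1 than Lrrfip2, at 0.1 kb, and its values are not given here. Of 42 neighbours of Mlh1, a list set by name that does not hold Tmie, 1 fell, and adjusted over the list alone 3 were higher and 2 lower (median 0.01, camera adjusted p = 0.948). No identity gene was called, but 46 of 48 had a negative fold (median -0.13, camera adjusted p = 5.57e-13; adjusted p = 0.584 with an estimated correlation). Pallidal and thalamic markers were called upwards (median 0.23, adjusted p = 0.000442; adjusted p = 0.428 with an estimated correlation; 3 higher adjusted over the list alone). DESeq2 called 53 genes and limma-voom 4. The count was 59 without WT M4, 39 without Mlh1-/- M1, 27 without Mlh1-/- F1, 25 without WT M3, 21 without Mlh1-/- M2, 8 without Mlh1-/- F2, 6 without WT F3 or M1, 5 without WT F2, F4 or M2, and 3 without Mlh1-/- F3 or WT F1.

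In Q140 Mlh1-/- against Q140 mice 12 genes were called, 5 higher and 7 lower. The rises were Cd93, an endothelial receptor gene, with 0.63 ± 0.13 (adjusted p = 0.0329), the interferon-induced gene Samd9l with 0.50 ± 0.10, the G-protein regulator gene Rgs14 with 0.34 ± 0.07, the kinase gene Rps6ka4 with 0.27 ± 0.05 and Lta4h, a leukotriene enzyme gene, with 0.14 ± 0.03. Beside Mlh1 and Lrrfip2, the falls included Ptpro, a receptor phosphatase gene, with -0.26 ± 0.05, Slc17a5 with -0.25 ± 0.05, Fut10 with -0.22 ± 0.04 and Kif26b, a kinesin gene, with -0.21 ± 0.04. Endothelial and mural markers were higher as a group (median 0.17, none of 19 called, 10 adjusted over the list alone, camera adjusted p = 6.67e-11; adjusted p = 0.248 with an estimated correlation; fry adjusted p = 0.0237). Interferon genes were too (0.20, 2 adjusted over the list alone, camera adjusted p = 2.82e-10; adjusted p = 0.337 with an estimated correlation), as were MHC class I genes (0.25, 3 adjusted over the list alone, camera adjusted p = 1.84e-07; adjusted p = 0.369 with an estimated correlation) and microglia markers (0.10, 1 adjusted over the list alone, camera adjusted p = 3.23e-06; adjusted p = 0.455 with an estimated correlation). Protocadherins were lower (-0.11, camera adjusted p = 7.12e-05; adjusted p = 0.581 with an estimated correlation) and identity genes higher (0.08, 2 adjusted over the list alone, camera adjusted p = 9.2e-05; adjusted p = 0.791 with an estimated correlation). Q140 Mlh1-/- F5 held the highest endothelial markers of its group, and without it the endothelial median was 0.12 with 6 members over the list alone. The MHC class I genes then had no member over the list alone, with a median of 0.20, and Samd9l stood at 0.42 without a call. The identity genes were not called as a list without Q140 M2 (adjusted p = 0.0619), and without Q140 F1 none of them passed over the list alone. The calls of Mlh1, Lrrfip2 and Slc17a5 were kept without each library in turn, and those of the other genes named here were lost without Q140 F1 or M2 or both, Cd93 at 0.56 and 0.61 and Rgs14 at 0.29 and 0.32. Further libraries mattered too: Cd93 had no call without Q140 F2 (0.64) or M3 (0.60). Samd9l, Lta4h and Kif26b each lost theirs without any of 7 libraries, some of them Q140 Mlh1-/- libraries. The count was 4 without Q140 F1, 6 without Q140 M2 and 8 without Q140 M3, and DESeq2 called 46 genes and limma-voom 13.

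Averaged over the 3 Mlh1 genotypes, the Q140 allele raised 1079 genes and lowered 1021, and 55 of these 2100 changed beyond 1.5-fold. Pipox fell by 0.59 ± 0.05 on the log2 scale (adjusted p = 2.08e-10), Krt9 by 0.71 ± 0.07 (adjusted p = 1.87e-09), Plk5 by 0.71 ± 0.08, Ddit4l by 0.66 ± 0.09 and Mafa by 0.80 ± 0.13. Kcng1, a potassium channel modifier gene, rose by 0.45 ± 0.05 (adjusted p = 5.22e-08), Slitrk6 by 0.64 ± 0.08, Tnnt2 by 0.59 ± 0.10, Pcdhga2, a gamma protocadherin gene, by 0.43 ± 0.06 and Htr2a by 0.42 ± 0.06. Limma on log2(FPKM + 0.1) called 2628 genes, 1809 higher and 819 lower, and 115 genes were called with 10 surrogate variables. Pipox had a call in each background, though in Mlh1-/- mice not without each library, with -0.61 ± 0.10, -0.69 ± 0.09 and -0.46 ± 0.09. Of the identity genes 31 of 48 fell and 1 rose, and adjusted over the list alone 36 fell and 3 rose, and 17 of 21 beta protocadherins rose, or 18 adjusted over the list alone. The Q140 effect did not differ between females and males by the edgeR test, which called 0 genes, with 589 at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. The 24 immediate early genes all had a more positive Q140 effect in females, with a median difference of 0.39, and none was called. No list test was run on this contrast. The mean of these genes had an SD of 0.364 to 0.531 log2 CPM between libraries of a group.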

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

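The tests below of label mix-ups, of the spread between libraries, of marker scores as covariates, of genes near Htt, of opposite-sex RNA and of shared codes were chosen only after the results were seen, while the score test was not. In each genotype group of 7 to 9 libraries, the gap from the most extreme library to its nearest neighbour was divided by the range of the group and compared with a 95% critical value, which chance passes in about 1 in 20 groups. Of 258 pairs of a gene and a group 22 passed, of 150 pairs of a list mean and a group 15, of 6 groups 0 for library totals, 0 for signature scores and 2 for a score of genes near Htt. That score was the mean signed log2 CPM of the 14 genes within 10 Mb of Htt that were called in Q140 Mlh1+/- vs Mlh1+/-.

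The Q140 effect on the signature score differed between backgrounds, by -0.236 in Mlh1-/- against Mlh1 wild-type mice, and the mean of the indirect-pathway list differed by 0.159 (exact permutation adjusted p = 0.0447). That list mean was 5.972 log2 CPM in WT, 5.782 in Q140, 5.876 in Mlh1-/- and 5.845 in Q140 Mlh1-/- mice. The lower level in Mlh1-/- than in WT mice is thus part of the difference. A larger spread in the Mlh1-/- comparison, whose median ratio of SD to the Q140 and WT pair was 1.07, is argued against by an upper bound of 63.3% of the Q140 effect retained, as spread alone would leave its mean unchanged. Cortical or choroid plexus tissue is argued against by the counts with marker scores as covariates, 2 against 767 genes, a ratio of 0.0026. Q140 labels mixed up in many Q140 Mlh1-/- mice are argued against by genes near Htt, whose score lay above every WT and Mlh1+/- library in 9 of 9, but a single mix-up is not, since Mlh1-/- F3 stood high (-0.64), with a signature score difference of -0.2248 without it. The permutation p of 0.000222 is what a weaker Q140 effect after loss of both Mlh1 alleles would give, although the genes of the score were chosen on these same libraries, and litter differences between groups stay open, untested.

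Mlh1 was far lower in Mlh1+/- F2 than in its group (4.23 against a median of 8.93 CPM, gap ratio 0.752), and Q140 Mlh1+/- F2 (4.83 CPM) and M3 (4.88 CPM) were low too. An Mlh1-/- animal recorded as Mlh1+/- is argued against only weakly by the lowest Mlh1+/- library, which lay 3.2 SD above the mean of the Mlh1-/- libraries. That library, at 4.23 CPM, lay nearer to the highest Mlh1-/- library (3.97 CPM) than to the median of its own group. RNA of the opposite sex is argued against by a highest share of 0.0225. An Mlh1+/- animal recorded as Mlh1 wild type stays open, because 1 Mlh1 wild-type library lay at or below the highest Mlh1+/- library. A haplotype of lower expression shared by animals of the same code could not be told apart from chance (one-sided permutation p = 0.0668 over 43 pairs). The test also used Mlh1-/- libraries, which lack a wild-type allele to show it. Of code 44, Mlh1+/- F2, Q140 Mlh1+/- F2 and Q140 F3 (9.81 CPM) were each the lowest of their group. Of code 45, WT M2 (9.34 CPM), WT M1 (11.1 CPM) and Q140 M1 (10.1 CPM) were low. Q140 Mlh1+/- M4 (8.67 CPM) of that code was not, nor was Mlh1+/- M1 (9.73 CPM) of code 43, which Q140 Mlh1+/- M3 shares. These codes were picked after the values were seen. No biological explanation that the design names was tested.

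The genes of the choroid plexus were high in WT M3: Ttr at 2530 against a median of 11.1 CPM (gap ratio 0.634), F5 at 51.2 against 1.75 CPM (0.725), Slc4a5 at 22.9 against 0.248 CPM (0.642) and the mean of the choroid plexus list (0.695). Q140 Mlh1-/- F5 stood highest for Cd93 with 23.7 against 10.7 CPM (0.652), Lrrfip2 with 25.4 against 20.9 CPM (0.538) and the means of the endothelial (0.601), astrocyte (0.559) and p53 lists (0.553), and lowest for Plk5 with 9.92 against 20.3 CPM (0.603). Mlh1-/- F3 stood highest for Tmem145 with 14.1 against 7.34 CPM (0.722) and Cd83 with 8.48 against 4.64 CPM (0.686), and lowest for Krt9 with 20.6 against 36.5 CPM (0.608) and the mean of the projection neuron identity list (0.687). Mlh1+/- F5 stood lowest for Krt9 with 21.5 against 35.3 CPM (0.609), Plk5 with 16.5 against 25.5 CPM (0.7) and Ddit4l with 21.8 against 34.7 CPM (0.585), and highest for the mean of the MHC class I list (0.513).

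Of the remaining genes, Plk5 was highest in Mlh1-/- M1 with 35.9 against 24.3 CPM (0.598), Gpr6 in Mlh1+/- M2 with 108 against 90.5 CPM (0.521), Pcdhb3 in Mlh1+/- F2 with 5.42 against 4.19 CPM (0.638), Whsc1 in Q140 M1 with 116 against 107 CPM (0.74), Zfyve28 in WT M1 with 126 against 105 CPM (0.606) and Dpysl5 in Q140 Mlh1-/- M4 with 82.2 against 64.3 CPM (0.517). Hsp90b1 was lowest in Q140 M2 with 231 against 274 CPM (0.584), and Tmem196 was lowest in Q140 M1 with 3.07 against 3.81 CPM (0.665) and in Q140 Mlh1-/- F2 with 2.58 against 3.33 CPM (0.55). Among list means, heat shock genes were highest in Q140 Mlh1+/- M1 (0.714) and in Q140 Mlh1-/- F4 (0.627), MHC class I genes in Q140 F2 (0.626), p53 genes in Q140 Mlh1+/- F1 (0.566), pallidal and thalamic markers in Q140 Mlh1+/- M1 (0.563), sterol genes in Q140 Mlh1+/- M3 (0.561) and oligodendrocyte precursor markers in Q140 Mlh1-/- M3 (0.544). Cell cycle genes were lowest in Q140 Mlh1+/- F3 (0.546) and neighbours of Mlh1 in Mlh1+/- F1 (0.533). The score of genes near Htt was lowest in Q140 M1 (-0.883, gap ratio 0.709) and highest in Mlh1-/- F3 (0.703) of their groups. For Q140 M1 that score lay within the WT range (-0.916 to -0.809), while 6 of the 7 Q140 libraries lay above every WT and Mlh1+/- library. The signature score of Q140 M1 was -0.13, above the highest WT library (-0.374), which is the side its label gives. The genes of the signature score were chosen with Q140 M1 counted as a Q140 library, so this is no independent check of its label, which stays open. Without Q140 M1 the signature score difference was -0.2601.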

How the results depend on the processing

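The marker-score covariates, the mixed model of the score, the fit without libraries at odds with their group, the permutation of list scores and the list tests without libraries that stood apart were tests chosen only after the data were seen. Where a value changed, the cause was not tested. The called count of each contrast is given. With plate row and column as factors it was 329 for Q140 vs WT, 234 for Q140 Mlh1+/- vs Mlh1+/-, 0 for Q140 Mlh1-/- vs Mlh1-/-, 0 for Mlh1+/- vs WT, 1 for Mlh1-/- vs WT and 4 for Q140 Mlh1-/- vs Q140. With 10 surrogate variables the counts of these contrasts were 9, 13, 8, 0, 2 and 2, and 115 for the averaged Q140 effect, and F5 (0.041) and Pcdhb9 (-0.044) turned direction in Q140 vs WT. At an adjusted p under 0.1 they were 1063 for Q140 vs WT, 1531 for Q140 Mlh1+/- vs Mlh1+/- and 85 for Mlh1-/- vs WT. DESeq2 gave 53 for Mlh1-/- vs WT, 1 for Q140 Mlh1+/- vs Q140, 46 for Q140 Mlh1-/- vs Q140 and 1 for the Mlh1-/- interaction. Only the compared groups gave 0 for Q140 Mlh1-/- vs Mlh1-/-, 0 for Mlh1+/- vs WT, 3 for Mlh1-/- vs WT and 4 for Q140 Mlh1-/- vs Q140. Limma on log2(FPKM + 0.1) gave 1, 0, 4 and 7 for these contrasts, and its balance of rises and falls is in the report. Limma-voom gave 0 for Mlh1+/- vs WT and 4 for Mlh1-/- vs WT. No filter on low counts gave 0 for Q140 Mlh1-/- vs Mlh1-/- and 1 for the Mlh1+/- interaction.

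Without a sex term 6 genes were called in Mlh1+/- vs WT, and Xist turned to -0.413 in Q140 Mlh1+/- vs Mlh1+/-. With the animal code as a random block 8 genes were called in Mlh1-/- vs WT. With cortical and choroid plexus scores the counts were 2 for Q140 Mlh1-/- vs Mlh1-/-, 0 for Mlh1+/- vs WT and 37 for Mlh1-/- vs WT, and without the libraries at odds with their group 1 for Q140 Mlh1-/- vs Mlh1-/-. The libraries left out there were WT M3, Q140 F2, Mlh1+/- F2 and Q140 Mlh1+/- F2 and M3. WT M2, Q140 M1 and Mlh1-/- F3 were kept, so that fit does not check these libraries. The 77 called list tests of 225 became 0 with an estimated correlation and 7 with fry. Exact permutation of list scores, run on 125 of them, called 7 where camera called 35. The difference of the score in Mlh1+/- mice, 0.005 in the report, was -0.1499 on the genes called in Q140 vs WT alone, where the selection favours the Q140 vs WT effect. That in Mlh1-/- mice kept its direction in every setting tried on the score. Plate row and column, surrogate variables and marker scores were not tried on it. RLE factors left it at -0.236, since a mean of rises less a mean of falls nearly cancels a scaling.

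Replicate numbers were checked as a pairing: libraries of the same sex and number correlated with a median r of 0.0133 over 107 pairs, 33 of them above 0.1, against -0.0427 over 370 pairs of other numbers, so the numbers do not pair the samples throughout. They follow the animal code in part: the F1 libraries of all groups but Q140 Mlh1-/- have code 39. A replicate block is thus in part a block for the code. With a replicate block all the same, the Mlh1-/- interaction held 1 call, the Mlh1+/- score difference was -0.0297 the Mlh1-/- score difference -0.2301 and the score of Mlh1-/- less that of WT mice 0.042 (exact p = 0.141). Libraries with the same animal code correlated with a median r of 0.154 over 41 pairs, 25 of them above 0.1, with a consensus correlation of 0.122. The permutations of the score do not use this code. A mixed model with the code as a random intercept gave score differences of -0.2359 ± 0.0626 (SE) in Mlh1-/- and 0.0093 ± 0.064 in Mlh1+/- mice.

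Without each library of the compared groups in turn, the counts ranged from 235 to 808 for Q140 vs WT, 577 to 1168 for Q140 Mlh1+/- vs Mlh1+/-, 0 to 5 for Q140 Mlh1-/- vs Mlh1-/-, 0 to 1 for Mlh1+/- vs WT, 3 to 59 for Mlh1-/- vs WT, 0 to 1 for Q140 Mlh1+/- vs Q140, 4 to 16 for Q140 Mlh1-/- vs Q140, 0 to 2 for the Mlh1-/- interaction, 0 to 0 for the Mlh1+/- interaction, 1742 to 2283 for the averaged effect and 0 to 0 for the sex difference. The score differences ranged from -0.2601 to -0.1974 in Mlh1-/- and from -0.0251 to 0.0432 in Mlh1+/- mice. Of the 107 gene calls followed under the alternatives, 103 of 103 that were tested kept their side of the threshold with DESeq2, 106 with RLE factors, 96 with limma-voom, 56 with plate row and column and 16 with surrogate variables. At 44 to 55.4 M counts per library, depth limits single genes of few counts such as Gm2420, at 1.57 ± 0.238 CPM in Q140 Mlh1-/- mice.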

Other observations

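The tests of genes near the engineered alleles were chosen only after the results were seen, while the splits of the samples were set before. The Q140 groups varied more than their controls in the signature score, with an SD 5.67 times that of WT in Q140 mice (exact permutation p = 0.0247, n = 7 and 8), 4.8 times that of Mlh1+/- in Q140 Mlh1+/- mice (exact p = 0.0114, n = 8 and 9) and 2.75 times that of Mlh1-/- in Q140 Mlh1-/- mice (exact p = 0.0487, n = 9 and 7). The score's genes were chosen for a Q140 effect in these libraries, and repeat length per animal is not in the labels.

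Called genes near the engineered alleles were counted as a test for DNA of another strain carried along with each allele. Within 10 Mb of Mlh1, 3 of 291 genes other than Mlh1 were called in Mlh1-/- against WT mice, against 9 of 21039 elsewhere (odds ratio 24.3, Fisher exact p = 0.000505), which is what such DNA would give, though an effect of the engineered allele on its neighbours would give the same. Within 10 Mb of Htt, 36 of 241 genes were called in the averaged Q140 effect, against 2064 of 21090 elsewhere (odds ratio 1.62, Fisher exact p = 0.0118), between the bounds set for and against such DNA, so that it cannot be told apart from effects of the expanded allele. In the single backgrounds 13 of 241 were called in Q140 vs WT (odds ratio 1.94, Fisher exact p = 0.03), 14 of 241 in Q140 Mlh1+/- vs Mlh1+/- (odds ratio 1.38, Fisher exact p = 0.259) and 2 of 241 in Q140 Mlh1-/- vs Mlh1-/-, where 2 of 21090 were called elsewhere (odds ratio 88.3, Fisher exact p = 0.000751). Without Mlh1 the 36 called genes near Htt kept a median of 0.725 of their Q140 effect, with quartiles of 0.315 and 1.14, against 0.377 for the 2064 called elsewhere. Such DNA would give an effect that does not depend on Mlh1, but no test compared these values, and the explanation stays open. No variant calls were at hand.

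The libraries of each contrast were also split at random into groups of the same sizes, 100 splits with the real one included, and the called genes were counted. In 4 contrasts only the real split, 1 of 100, reached the real count. These were Q140 vs WT (real count 615, highest other 219) and Q140 Mlh1+/- vs Mlh1+/- (916 and 179). The others were Q140 Mlh1-/- vs Q140 (12 and 2) and the averaged Q140 effect (2100 and 1). A share below 1 of 100 could not be seen with this number of splits. The splits did not keep sex, plate position or animal code in balance. For Q140 Mlh1-/- vs Mlh1-/- 4 of 100 splits called as many as the real 4, and a split called 12. For Mlh1+/- vs WT 11 of 100 splits called as many as the real 1 (highest other 20), and for Mlh1-/- vs WT 11 of 100 called as many as the real 13 (highest other 241), so that chance was not excluded for these counts. A structure of the samples other than genotype could give such high counts, as could correlated genes, and no cause was tested. For the contrasts with a real count of 0, all 100 splits trivially called as many, with a highest other of 1 for Q140 Mlh1+/- vs Q140, 43 for the Mlh1+/- interaction, 6 for the Mlh1-/- interaction and 184 for the sex difference. The splits concern counts, so the fall of Mlh1 itself, at -2.19 on the log2 scale in Mlh1-/- against WT mice, is not put in doubt by them.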
